A study of Mus musculus with 7 samples.

How the data were processed

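A pair of kinds of processed values were used, a table of gene expression with a differential test and a list of MyoD peaks. Of the 7 samples in the series, each in a group of its own by its labels, 3 entered: RNA of empty-vector myoblasts in growth medium, RNA of empty-vector myotubes after 48 hours of differentiation, and MyoD ChIP of 2-day myotubes. The 4 histone ChIP samples were not analysed here. The MyoD sample is described in its label as taken from an earlier sample. The antibodies that the labels' protocol lists do not include one against MyoD. The labels' protocol states sequencing in duplicates, but how duplicates were combined is not given in the sources used here. Myoblasts came from satellite cells of mice of 4 to 6 weeks, per the labels' protocols.

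Expression values were FPKM as deposited, 1 per gene and condition, in the layout of a gene table of Cuffdiff, which the submitters' processing notes name together with CASAVA 1.7.0 and the mm9 build. The aligner, the annotation release, the normalization setting and the Cuffdiff version are not given in the sources used here. The authors' p-values and q-values come from their Cuffdiff test. A gene was taken as called where the authors marked it significant, which went with a q of at most 0.05 and a test status of OK. The authors deposited it in 2 copies with identical contents and 1 copy was used. The authors' log2 fold change and test statistic columns carry the largest possible number for genes at 0 in a condition, and such genes were left out of steps that need a finite value. Of 37975 genes, 15966 were tested, 21575 were not tested, 330 had too little data and for 104 the test had failed, per the status given by the authors. Gene symbols were those of the table, and 32917 of its identifiers were found in the name table of another build, from which no coordinates were used. Mrln, a list member, was not found in the table by symbol.

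Peaks were called with MACS, per the file headers, and version 1.3.7 is in the submitters' processing notes. The headers give a tag size of 36, a band width of 150, a model fold of 16, a p-value threshold of 1.00e-05 and an effective genome size of 1.87e+09. They give 8637045 tags in the treatment, 46.9% at unique positions, and 9129012 in the control, 47.9% at unique positions. Tags per peak are counts, per the file headers. The p score is 10 times the negative log10 of the p-value, per the file headers, and fold enrichment is a ratio to the regional background, per the file headers. The false discovery rate is a percent that the authors' caller estimated from the control. What the control was is not given in the sources used here. The list came from 1 call on 1 treatment, so no overlap of replicates was possible. Coordinates are printed from 1, and the summit is the peak start plus the summit offset minus 1.

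The standard error of a log2 fold change was recovered as the size of the authors' log2 fold change divided by their test statistic. Recomputed p-values differed from those deposited by at most 2.68e-06 over 15416 genes. The median of these errors was 0.65, with 0.51 for genes with a mean FPKM of at least 10 and 0.76 below. No test of differential expression was run on replicates, since each condition has 1 value. Relative depth was read from 2931 untested genes above 0 in both conditions, where single reads set the values: the most frequent log2 ratio, 0.114, was shared by 191 genes.

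Before the data were examined, 25 gene lists with 412 distinct genes were fixed. For each, counts of calls are given over all tested genes and adjusted over the list alone, by the Benjamini-Hochberg method on the authors' p-values of its tested members. The list median of log2((FPKM 2-day + 1)/(FPKM growth + 1)) used tested genes with a mean FPKM of at least 1 (15146 genes). It was placed among 10000 random lists of the same size drawn within 20 bins of mean FPKM. A list outside the central 95% is described as standing apart, which describes these libraries and is not a p-value across genes. Immune and Schwann or neural markers had 2 members each above that minimum and were given no median.

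Peaks were joined to genes through the loci of the expression table. A gene had a peak where a summit lay in its locus or within 10 kb. In that table a locus is a merged region: 4851 tested genes (30.4%) share theirs with another tested gene, 1260 have a locus above 200 kb, and the longest, of 4435365 bp, is shared by 70 tested genes, all of which count its peaks. Shares with a peak were compared with 10000 random gene sets matched in 10 bins of mean FPKM by 10 bins of locus length, over 15930 tested genes on chromosomes 1 to 19 and X. Peak location was compared with 10000 random positions. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only. E-box motifs in peaks, which the title of the series concerns, were not analysed here, since that needs the sequence of the mm9 genome.

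Genes were named by a rule fixed before the data were examined. It took genes called by the authors with a larger FPKM of at least 10 and a smaller of at least 0.1, and of these the 12 largest rises and 12 largest falls. It added up to 4 members per list with the largest absolute log2 fold change among those with an FPKM of at least 10, called or not, then Myod1, Myog, Pax7, Myf5, Ckm and Myh3, and the 10 peaks with the highest fold enrichment. This gave 104 genes. Not every member behind a small count is reported here. Other genes named beside a small count, genes near a peak, the chaperones Hspa5 and Hsp90b1, and the ranking of peaks by tags were chosen after their values were seen.

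Alternatives fixed beforehand changed the q threshold, the minimum fold, filters on low values, the pseudocount, centring of list ratios, the peak threshold, the window around loci, the definition of overlap, the matching and the measure of height. Added after seeing the data were calls centred on the median of all tested genes, genes with a locus of their own of at most 200 kb, the analysis without chromosomes 14 and X, and matching on the FPKM of 2-day myotubes. A locus of their own means 1 shared with no other tested gene, and it may still be merged with untested genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

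The list percentile, the occupancy comparison and the calls after centring were tested on simulated data. Peak location, shares by number of summits and the comparison of peak height with expression were not. Among 200 simulated lists of 20 genes from 15146, 3.5% with no shift fell outside the central 95%, 70.0% with a shift of 0.5 log2 and 99.5% with a shift of 1. Members of these simulated lists were drawn at random with independent noise, so lists of genes that change together were not covered. For the occupancy comparison, 200 sets drawn from the genes called higher fell outside in 3% of draws with no added peaks, 91.5% with 10 points added and 100% with 20 points. Sets drawn from the genes called lower gave 4%, 89.5% and 100%. An earlier form of this test, which drew members in proportion to locus length, failed: with no added peaks 85% of its sets fell outside, on average 8.83 points too high. The matching was kept as fixed beforehand and the simulation was redone on the called genes. Its calibration does not extend to sets made mostly of very long loci, and it was not tested for the gene lists. Simulated peaks were drawn for each gene on its own from locus length, while real genes with a shared locus share its peaks. Calibration under that dependence, which the called genes carry, was therefore not tested. For calls after centring, 50 simulations over 15416 genes with 200 genes raised by 3 log2 recovered 80.9% of them on average, with 9.04 false calls.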

Results

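The series profiled mouse primary myoblasts, the cultured progeny of muscle satellite cells sorted from mice of 4 to 6 weeks, and the multinucleated myotubes they form after 48 hours in medium with 5% horse serum. It held 7 samples, 1 per group. Polyadenylated RNA was sequenced from growing myoblasts and from 2-day myotubes, both carrying an empty vector. MyoD, the basic helix-loop-helix factor that drives muscle differentiation, was mapped by chromatin immunoprecipitation (ChIP) in 2-day myotubes. The remaining 4 samples, ChIP for 3 histone marks and for histone H3, were not analysed here.

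The authors' deposited table of expression listed 37975 genes, each with 1 FPKM value (fragments per kilobase of transcript, scaled to the fragments mapped) per condition, and tested 15966 of them. Read totals were not given in the sources used here, so absolute depth was unknown. Among low genes the most frequent ratio of the 2 values put the myoblast library at 1.08 times the depth of the myotube library. That reading holds only if FPKM was scaled to library depth, and the normalization setting is not given in the sources used here. The MyoD peak list came from 8637045 ChIP tags and 9129012 control tags, of which 4049890 and 4371189 were unique. With 1 value per condition no difference had a replicate check here. Errors of log2 fold changes are the standard errors (SE) implied by the authors' test statistics, and log2 values are 2-day myotubes over growing myoblasts.

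The first comparison asked which genes changed as myoblasts became myotubes. In the authors' deposited table Ckm, the muscle creatine kinase, rose from 49.4 to 1453 FPKM (log2 4.88, SE 0.81, q = 6.84e-08), and Myh3, the embryonic myosin heavy chain, rose from 111 to 2362 (log2 4.41, SE 0.61, q = 6.39e-11). Myog, the myogenic factor of terminal differentiation, rose from 130 to 1207 FPKM (log2 3.21, SE 0.80, q = 0.000625) in the authors' deposited table. Pax7, the satellite cell factor, fell from 48.5 to 6.71 (log2 -2.85, SE 0.60, q = 3.75e-05) in the authors' deposited table. Myod1 itself was listed at 895 FPKM in myoblasts and 293 in myotubes and was not called (log2 -1.61, SE 0.83, q = 0.154, authors' deposited table).

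By the authors' deposited table, 1041 genes were called higher and 2769 lower in myotubes, so that 27.3% of the 3810 calls were higher. The FPKM of tested genes summed to 1.63545e+06 in myoblasts and 1.63461e+06 in myotubes. With sums this close, large rises of abundant genes can lower the relative values of other genes. Whether this gave the excess of lower calls and the negative median that follows was not tested. The median log2 fold change of the 15416 tested genes above 0 in both conditions was -0.41. After centring the authors' log2 fold changes on that median, an alternative chosen after seeing the data, 1587 genes were higher and 1630 lower, a share of 49.3% higher. Centring puts as many of these genes above 0 as below, so a near-even split of calls is partly set by it. It does not show the true balance. Of the deposited calls, 1040 higher and 1630 lower were kept. Among the 104 genes named here from the deposited table by the rule fixed beforehand, Myf5, Jun, Myc and Npm1 lost their lower call after centring, and Cdkn2c and Dok7 gained a higher one. On the log2(FPKM + 1) scale used for the medians of gene groups, the median of all genes used was -0.37.

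Rises and falls were ranked among called genes with a larger FPKM of at least 10 and a smaller of at least 0.1. The 12 largest rises in the authors' deposited table ran from 30.2-fold to 75.2-fold. They were led by Rap1gap2, a GTPase-activating protein for Rap1, at 4.40 FPKM in myoblasts and 331 in myotubes (log2 6.23, SE 0.57, q listed as 0, authors' deposited table). The others were Pappa2, 2310043M15Rik, Gm14290, Trp63, Vgll2, Gabrr2, Adamtsl2, Tekt5, Tecrl, Cmbl and Asb2. Vgll2, a TEAD cofactor of skeletal muscle, rose from 0.283 to 12.3 FPKM, and Asb2, a ubiquitin ligase subunit, from 3.30 to 99.6 in the authors' deposited table. The 12 largest falls ran from 18.9-fold to 197-fold in the authors' deposited table. Lmbr1 fell from 310 to 1.57 FPKM (log2 -7.62, SE 0.83, q listed as 0, authors' deposited table), and the others were 2610020H08Rik, Defb36, Dnm3os, Gas2, BC030867, Neil3, Mybl1, Pif1, Adam8, Gm15654 and Slc8a1. Adam8, a membrane metalloprotease, fell from 23.1 to 1.08 and the DNA glycosylase gene Neil3 from 12.4 to 0.566 in the authors' deposited table. Of the 12 falls, 5 were at genes that share their locus with another tested gene, where reads of overlapping genes can be hard to separate, and Defb36 among them had an SE of 2.13 in the authors' deposited table.

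Genes of the contractile machinery rose together. Of 37 tested sarcomere genes, 36 were called higher and 0 lower in the authors' deposited table, and 37 were higher when adjusted over the list alone. Tnnc2, the fast troponin C, rose from 311 to 7453 FPKM (log2 4.58, SE 0.50) in the authors' deposited table, and the M-band gene Myom2 rose from 46.3 to 1101 (log2 4.57, SE 0.41). Tcap, the titin cap, rose from 11 to 251 FPKM and Mybph, a myosin binding protein, from 105 to 2449 in the authors' deposited table. The remaining tested member, Actn3, was at 169 and 550 FPKM. The median log2 ratio of the list was 3.80, above all 10000 random lists matched on mean expression.

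Excitation-contraction coupling genes, which link membrane depolarisation to calcium release, had 14 of 19 tested members called higher and 0 lower in the authors' deposited table (16 and 0 adjusted over the list alone), with a median of 2.97. Atp2a1, the calcium pump of fast fibres, rose from 95 to 2077 FPKM (log2 4.45, SE 0.48), and Sln, its small inhibitor, from 2.05 to 54.1 (log2 4.72, SE 0.82) in the authors' deposited table. Casq2 rose 18.7-fold and Cav3 18.8-fold in the authors' deposited table. Muscle metabolism genes had 13 of 14 called higher in the authors' deposited table, also 13 adjusted over the list alone, and a median of 2.99. Slc2a4, the insulin-responsive glucose transporter, rose from 3.65 to 74.4 FPKM, Cox6a2 from 41.3 to 677 and Ampd1 from 0.941 to 14.2 in the authors' deposited table, while Ppargc1a, at 6.96 and 3.53, was not called. Dystrophin complex and sarcolemma genes had 7 of 12 called higher and 0 lower in the authors' deposited table (8 and 0 adjusted over the list alone), with a median of 1.81. Dmd, which encodes dystrophin, rose from 3.03 to 22.9 FPKM (log2 2.92, SE 0.49) and Capn3, a muscle calpain, from 18.2 to 252 (log2 3.79, SE 0.77) in the authors' deposited table.

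Among 12 tested myoblast fusion genes, 5 were called higher and 2 lower in the authors' deposited table, the same counts adjusted over the list alone, and the median was 0.49. Both fusogens rose in the authors' deposited table, Tmem8c (myomaker) from 143 to 1913 FPKM (log2 3.75, SE 0.91) and Gm7325 (myomixer) from 11.3 to 111 (log2 3.30, SE 0.67). Jam2, Cav3 and Nfatc2 were the other genes called higher, and Cd9 and Dock1 were called lower in that table, a call that neither kept after centring. At the neuromuscular junction 3 of 10 genes, Chrng, Ache and Colq, were called higher in the authors' deposited table, also 3 adjusted over the list alone. Chrng, the fetal acetylcholine receptor subunit, rose from 137 to 327 FPKM (log2 1.26, SE 0.37, authors' deposited table), while Chrnd, at 99.3 and 179, and Lrp4, at 30.3 and 49.8, were not called. The junction list had a median of 0.77, at percentile 99.8 of its random lists, and the fusion list stood at percentile 99.

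Myogenic regulators split. Of 12 tested, 5 were called higher (Myog, Myf6, Mef2c, Mef2d and Hdac9) and 5 lower, among them Myf5, in the authors' deposited table, with the same counts adjusted over the list alone. After centring, 5 were higher and 2 lower. Mef2c, a partner of MyoD at muscle genes, rose from 15.4 to 221 FPKM (log2 3.85, SE 0.59) in the authors' deposited table, and Myf5 fell from 55.4 to 14.4 (log2 -1.94, SE 0.66). The list's median was -1.22, at percentile 0.22, while its mean was 0.03. Without the filter on low genes the median was -0.50, at percentile 17.1, no longer apart from random lists.

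Markers of satellite cells and undifferentiated myoblasts had 9 of 15 members called lower and 2, Spry1 and Heyl, called higher in the authors' deposited table (11 and 2 adjusted over the list alone). Met, the hepatocyte growth factor receptor, fell from 125 to 14.6 FPKM (log2 -3.09, SE 0.40), Cxcr4 from 77.5 to 10.6 and Vcam1 from 61.4 to 8.47 in the authors' deposited table. Among antagonists of MyoD 6 of 11 were called lower and 0 higher in the authors' deposited table (8 and 1 adjusted over the list alone). Id1, Id2 and Id3, whose products sequester the E-protein partners of MyoD, were among them, and Id4, at 1.25 and 0.475 FPKM, was not called in the authors' deposited table. Id3 fell from 704 to 98.2 FPKM (log2 -2.84, SE 0.48), Id1 from 300 to 41.6 and Id2 from 177 to 25.5 in the authors' deposited table. Snai2, an E-box repressor, fell from 34.6 to 5.79 in the authors' deposited table. The medians were -1.57 and -1.73, at percentiles 0.01 and 0.04.

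Proliferation genes fell as a block. All 25 mitosis genes and 28 of 30 genes of DNA replication were called lower in the authors' deposited table, also 25 and 28 adjusted over the list alone, and 25 and 24 were lower after centring. Bub1b, a spindle checkpoint kinase, fell from 93.2 to 8.38 FPKM (log2 -3.48, SE 0.45), Plk1 from 43.9 to 4.10 and Cenpa from 99.1 to 9.75 in the authors' deposited table. Mcm6, a subunit of the replicative helicase, fell from 81.5 to 8.58 (log2 -3.25, SE 0.70) and Ccna2, cyclin A2, from 71.8 to 7.56 in the authors' deposited table. The medians of -2.92 and -2.34 lay below all random lists. Of 11 genes of cell cycle exit, Cdkn1a, Cdkn1c and Gadd45a were called higher and 0 lower in the authors' deposited table, the same adjusted over the list alone, with 6 higher after centring. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 470 to 2374 FPKM (log2 2.34, SE 0.76) and Cdkn1c from 3.08 to 33.6 in the authors' deposited table. The median of that list was 0.86, at percentile 99.9.

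**Figure D1:**
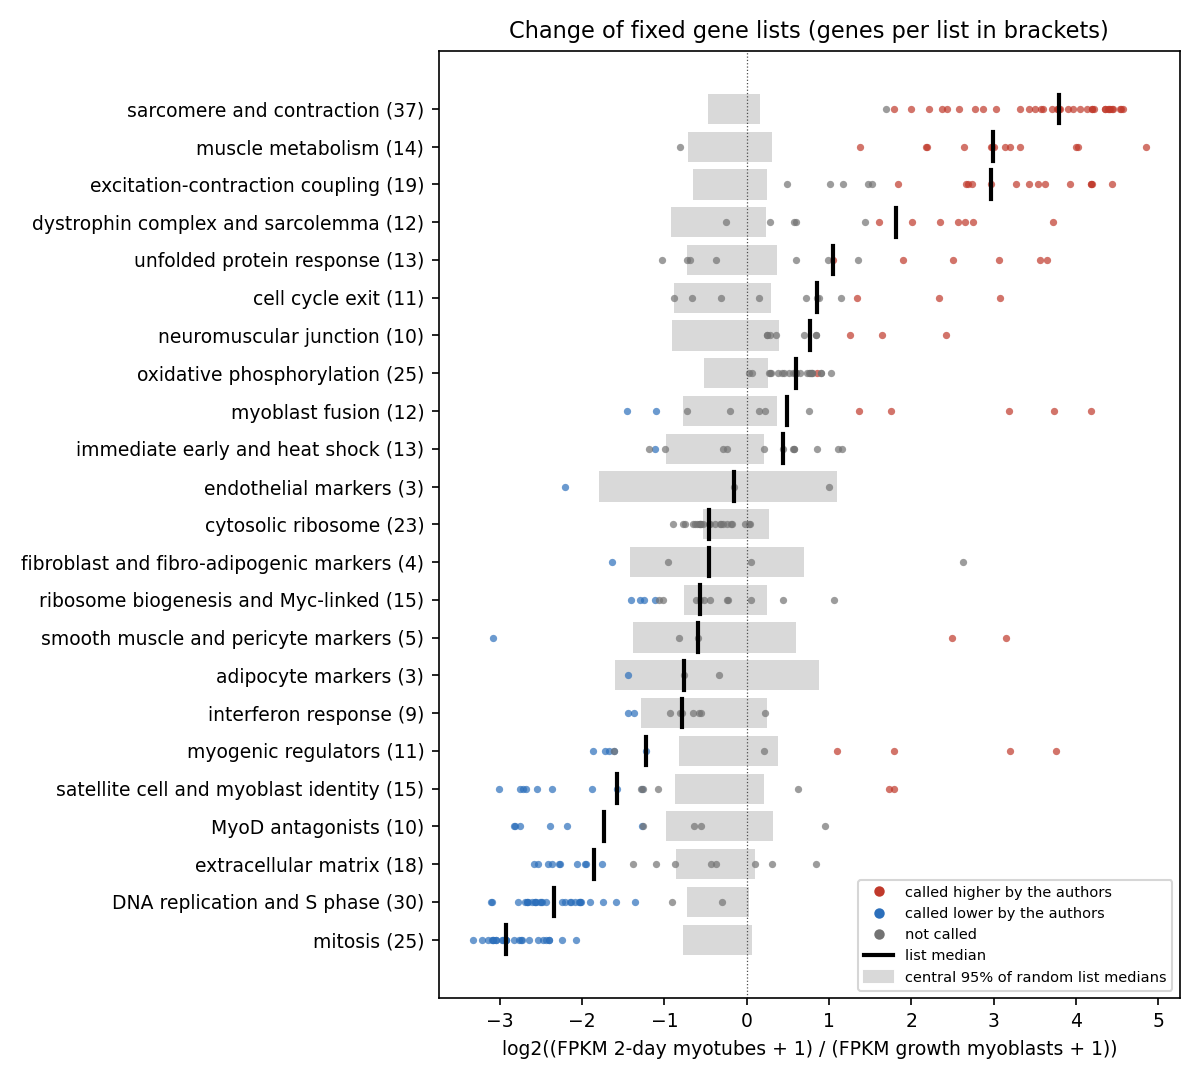
Each row is a gene list fixed before the data were examined, with the number of genes used; the horizontal axis is log2((FPKM in 2-day myotubes + 1) / (FPKM in growing myoblasts + 1)). Points are genes coloured by the authors' call, black bars list medians and grey bars the central 95% of 10000 random list medians; sarcomere genes have a median of 3.80 and mitosis genes of -2.92, while the median of all genes used was -0.37.

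Extracellular matrix genes had 10 of 18 called lower and 0 higher in the authors' deposited table (11 and 0 adjusted over the list alone), with a median of -1.85. Tnc, tenascin C, fell from 84.9 to 13.4 FPKM (log2 -2.67, SE 0.31), Col3a1 from 82.2 to 13.3 and Col5a2 from 102 to 18.3 in the authors' deposited table. Genes of the unfolded protein response had 6 of 13 called higher and 0 lower in the authors' deposited table (8 and 1 adjusted over the list alone), with a median of 1.04 at percentile 99.99. Those called were Atf3, Trib3, Herpud1, Chac1, Ddit3 and Xbp1. Herpud1, an endoplasmic reticulum degradation factor, rose from 60.3 to 514 FPKM (log2 3.09, SE 0.30), Trib3 from 8.17 to 107 and Atf3 from 1.76 to 33.7 in the authors' deposited table. The chaperone genes Hspa5, at 634 and 965 FPKM, and Hsp90b1, at 656 and 396, were not called.

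Oxidative phosphorylation genes stood at percentile 99.9 with a median of 0.60, yet only Ndufv1 of 25 was called higher in the authors' deposited table (1 adjusted over the list alone, 6 after centring). Ndufv1, a complex I subunit, rose from 330 to 597 FPKM (log2 0.86, SE 0.24, authors' deposited table), and Cox5b was at 267 and 544, not called. None of 23 cytosolic ribosome genes was called in the authors' deposited table (0 adjusted over the list alone). Their median was -0.45, inside the random range at percentile 5.98, and -0.08 relative to the median of all genes. Ribosome biogenesis genes had 4 of 15 called lower in the authors' deposited table, Npm1, Nop56, Dkc1 and Myc, also 4 adjusted over the list alone and 2 after centring, and a median of -0.56 at percentile 10.5. Immediate early and heat shock genes, which respond to handling, had a median of 0.44 at percentile 99.6, while the 1 call in the authors' deposited table was lower, for Jun (76.7 to 34.8 FPKM). No member passed when adjusted over the list alone, and after centring 2 were higher and 0 lower. Interferon response genes had 2 of 10, Irf9 and Ifit1, called lower in the authors' deposited table (2 adjusted over the list alone, 0 after centring) and a median of -0.79 at percentile 24.6.

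Apart from Acta2 and Rgs5, no listed marker of another cell type had a mean above 22.4 FPKM. Few members were tested, 4 for fibroblasts, 3 each for adipocytes and endothelium, 4 for immune cells, 5 for Schwann cells and neurons and 6 for smooth muscle and pericytes. Calls lower in the authors' deposited table were Thy1, Lpl, Pecam1, Cd68, Cd14, Mbp, Nefl and Rgs5, and calls higher were Acta2 and Abcc9. Adjusted over the list alone, fibroblast markers had 1 higher and 1 lower, adipocyte and endothelial markers 1 lower each, immune and Schwann or neural markers 2 lower each, and smooth muscle markers 3 higher and 2 lower. The highest mean of any fibroblast marker was 2.59 FPKM, of any adipocyte marker 8.99, of any endothelial marker 5.12, of any immune marker 22.4 and of any Schwann or neural marker 8.48. Acta2, the smooth muscle actin that differentiating myoblasts also express, rose from 227 to 2025 FPKM and Rgs5, a pericyte marker, fell from 73.1 to 7.72 in the authors' deposited table. The medians of the fibroblast, adipocyte, endothelial and smooth muscle lists were -0.45, -0.76, -0.16 and -0.59, at percentiles 52, 28.7, 71.9 and 31.7. For fibroblast and smooth muscle markers the means, 0.02 and 0.23, had the opposite sign.

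Of 23 lists with a median, 10 lay above and 6 below the central 95% of their random lists. A count of 1.15 outside would hold for independent lists of unrelated genes. These lists share some members and hold genes that may change together, so the count that chance would give them is not known.

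The second comparison described where MyoD was bound. The authors' list held 10756 peaks in mm9 coordinates on chromosomes 1 to 19 and X, with a median width of 426 bp, a median of 14 tags (range 7 to 707) and a median fold enrichment of 15.3 (range 3.82 to 87.2). Tags, fold enrichment and p are the authors' values for each peak. The authors' false discovery rate was at most 5% for 2086 peaks (19.4%) and at most 1% for 1 peak, that at Myod1. Peaks held 187373 tags, equal to 4.63% of the unique ChIP tags.

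By fold enrichment the highest peak lay on chromosome 11 from 7271960 to 7272410, with 87.2-fold enrichment from 22 tags, 158117 bp from the nearest tested gene, Igfbp3. Next came a peak inside the Gpr155 locus on chromosome 2 from 73189512 to 73190248, with 79.6-fold enrichment from 44 tags. Gpr155 rose from 2.34 to 11.6 FPKM and Igfbp3 fell from 197 to 55.5 in the authors' deposited table. The nearest tested genes of the other peaks among the top 10 were Zfr, Lphn2, Mrps9, Ambra1, Gap43, Rgmb, Lysmd4 and Gm8814. Only 3 of these 10 peaks lay inside a tested locus (Gpr155, Zfr and Ambra1), and 7 lay more than 50 kb from one. Their false discovery rates ran from 2.78% to 12.5%, the latter at Gpr155.

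Ranking by tags, chosen after the values were seen, gave different places. The Myod1 locus carried the peak with the most tags, 707, on chromosome 7 from 53631485 to 53633948, with 10.3-fold enrichment. The next, with 231 tags, lay on chromosome 8 from 126415781 to 126420366, inside a merged locus shared by 70 tested genes that include Acta1, the skeletal actin gene. A peak of 212 tags on chromosome 1 from 136089489 to 136093091 lay in the locus shared by Adora1 and Mybph. Further peaks lay near Mir133b (190 tags), inside the locus of Actc1, the cardiac actin gene (162 tags), near Tnrc18 (117), in Nctc1 (110), Olfml2b (105) and Plec (100), and 93 bp from Chrna1, an acetylcholine receptor subunit (99). The authors' false discovery rates of these 10 peaks ran from 0% at Myod1 to 50% at Olfml2b, with 13.99% at Nctc1. Across all peaks fold enrichment and tags ran opposite, with a Spearman rho of -0.26.

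Peaks were not evenly spread over chromosomes. Chromosome 14 carried 168 peaks, or 1.34 per Mb, and chromosome X 136, or 0.816 per Mb, while the other autosomes carried 3.38 to 6.22 per Mb. Median fold enrichment was 20.0 on chromosome 14 and 19.9 on X, against 14.4 to 15.9 on the other autosomes. Median tags were 10 on chromosome 14 and 11 on X, against 13 to 15.

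**Figure D2:**
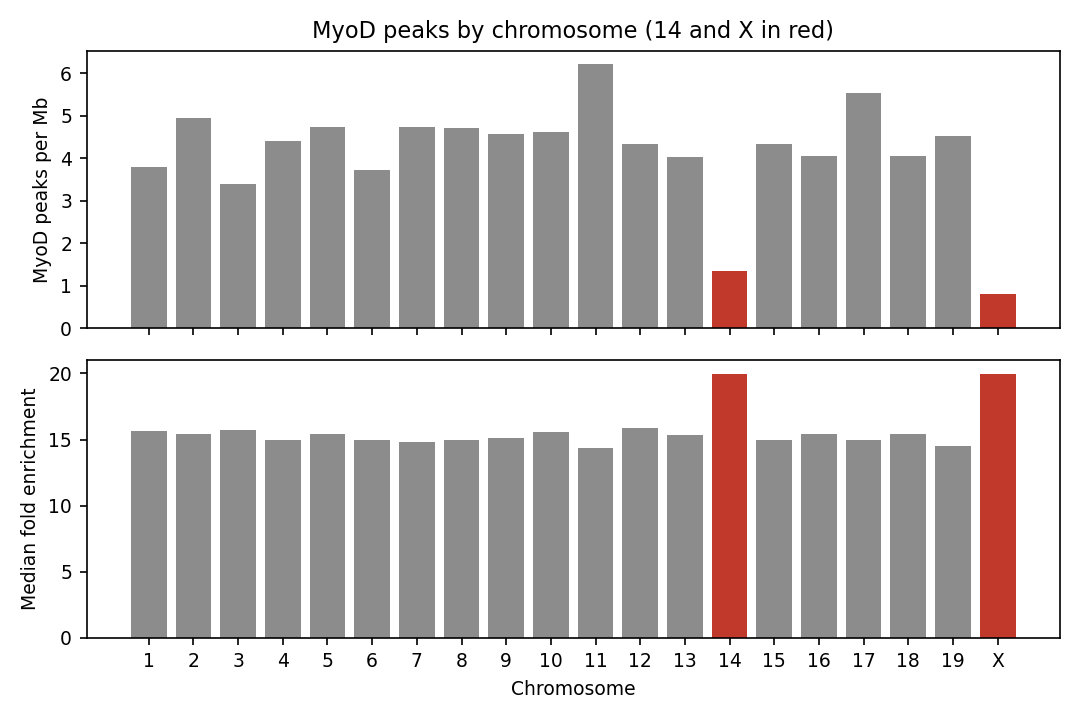
Upper panel: MyoD peaks per Mb for each chromosome; lower panel: median fold enrichment of the peaks as the authors gave it. Chromosomes 14 and X, in red, have 1.34 and 0.816 peaks per Mb with median fold enrichments of 20.0 and 19.9.

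Summits lay at tested genes more often than random positions did. Of 10756 summits, 7199 (66.9%, exact 95% binomial interval 66.0 to 67.8) fell in or within 10 kb of the locus of a tested gene, against 35.8% of 10000 random positions (34.8 to 36.7). For all genes of the table the shares were 77.1% and 56.2%. Random positions were drawn uniformly over each chromosome, and sequence where tags cannot be placed was not left out. Whether that lowered their share was not tested. Intervals cover counting error only. Loci were those of the expression table and carried no strand, so promoter and downstream peaks were not separated, and exons and introns were not used here.

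The third comparison, named in the series' design, joined MyoD binding with expression. The RNA came from cells with an empty vector, while the MyoD sample is described in its label as taken from an earlier sample. Binding and expression may therefore come from different cultures. Of 1040 genes called higher on these chromosomes, 609 (58.6%, exact 95% binomial interval 55.5 to 61.6) had a summit within 10 kb. Random genes matched on mean FPKM and locus length averaged 43.4%, with a central 95% of 40.7 to 46.2, and all 10000 random sets lay below the observed share. Of 2767 genes called lower, 1061 (38.3%, 36.5 to 40.2) had a summit, below all of their matched sets (42.5%, 40.9 to 44.1). Of 12123 genes not called, 37.3% had one. Without matching, the share of genes called lower was not apart from random sets of tested genes (38.9% on average, percentile 24.6). Matched on 2-day FPKM in place of the mean, an alternative chosen after seeing the data, it was at percentile 0.64 of sets averaging 40.2%.

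**Figure D3:**
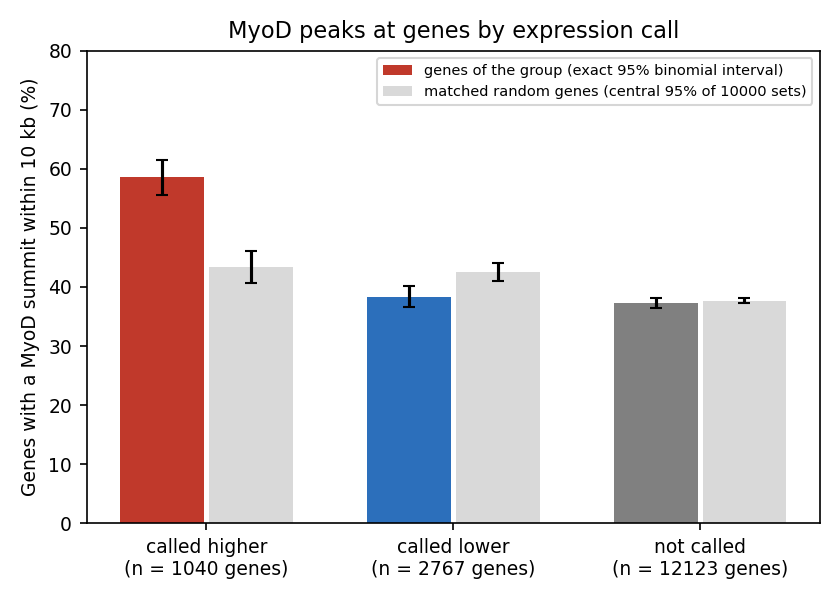
Share of genes with a MyoD summit within 10 kb of their locus, in percent, for genes called higher, lower or neither by the authors, beside matched random genes in light grey. Error bars are exact 95% binomial intervals for the groups and the central 95% of 10000 random sets; the genes called higher stand at 58.6% against 43.4%.

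Some muscle gene groups carried peaks more often than matched genes, and others did not stand apart. Sarcomere genes had a summit within 10 kb in 31 of 37 (83.8%, matched lists 51%) and excitation-contraction coupling genes in 18 of 19 (94.7%, matched 51%). Neuromuscular junction genes followed with 8 of 10 (80%, matched 46.9%) and fusion genes with 10 of 12 (83.3%, matched 54.9%). Sarcomere and coupling genes lay above the central 95% of matched lists. Junction and fusion genes, and the adipocyte markers, whose 3 tested members Lpl, Pparg and Cebpa all had a peak, lay at its upper end, and stood apart only by percentiles that split ties evenly (98.1, 99.4 and 98.3). The comparison was not tested by simulation for any gene list. Among genes with a locus of their own of at most 200 kb, chosen after seeing the data, sarcomere genes stood at 75% against 43.3% and coupling genes at 100% against 50.6%. With a window of 0 kb or of 50 kb the junction, fusion and adipocyte lists no longer stood apart, and among peaks with a p score of at least 100 the coupling and fusion lists did not, nor the adipocyte markers, which had 0%. Muscle metabolism genes had a peak in 9 of 14, satellite cell markers in 10 of 15, MyoD antagonists in 7 of 11, dystrophin complex genes in 8 of 12 (66.7%, matched 61.5%), myogenic regulators in 6 of 12 (50%, matched 47.9%) and mitosis genes in 6 of 25, inside their matched ranges with this window. Of these, metabolism, satellite cell and antagonist genes also lay at the upper end of the range, at percentiles 95.4, 97.0 and 96.8. With own loci of at most 200 kb MyoD antagonists stood above theirs (75% against 20%, percentile 99.96) and so did metabolism genes (66.7% against 35.8%, percentile 97.85), and with a 50 kb window metabolism genes stood above (percentile 98.5) and mitosis genes below (percentile 1.39). Among peaks with a p score of at least 100, DNA replication genes, mostly called lower in the authors' deposited table, stood above theirs, at 30% against 13.2% (percentile 99.5). With all peaks they lay inside their range, at 46.7% against 41.3% (percentile 73.1). They also did so with windows of 0 kb and 50 kb and with own loci (35.3% against 33.3%, percentile 57.7). Their members Cdt1 and Gins2 each had 93 summits within 10 kb, the count also found for Acta1 in its merged locus. Cdh15, among the 10 fusion genes with a peak, had the same count. With own loci of at most 200 kb the fusion list stood at 85.7% against 44.1% (percentile 98.78).

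Individual genes did not all follow their group. Myh3 had 6 summits within 10 kb and Rap1gap2 had 5, while Ckm, Acta2, Trp63 and Vgll2, all called higher in the authors' deposited table, had 0. Id1 and Id3 had 3 summits each and Pax7 had 2, all called lower in the authors' deposited table. Myog had 1 summit, of 23 tags and 9.72-fold enrichment. Of the 12 largest rises 7 had a peak, and of the 12 largest falls 4. The Chrnd and Chrng loci, which lie side by side on chromosome 1, shared a peak of 83 tags.

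The share of genes called higher grew with the number of summits. It was 4.43% (exact 95% binomial interval 4.03 to 4.86) of 9733 genes with 0 summits, 8.21% (7.33 to 9.17) of 3543 with 1, 10.1% (8.53 to 11.9) of 1316 with 2 and 13.8% (12 to 15.8) of 1338 with 3 or more. The share called lower was 17.5%, 18%, 17.1% and 14.7%. Median locus length also grew, from 17.5 kb with 0 summits to 150 kb with 3 or more, and this comparison was not matched on length.

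The series' title names an affinity landscape, and peak height was compared with expression on that account. Across 6197 genes with a peak, which are not independent replicates, the highest fold enrichment within 10 kb had a Spearman rho of -0.03 with the log2 ratio. With genes ranked by fold enrichment and cut into 3 equal groups, from lowest to highest, 9.68%, 10.9% and 8.91% of genes were called higher. With tags as the measure of height the rho was 0.16, and the shares were 5.57% (4.62 to 6.64), 8.57% (7.40 to 9.86) and 15.4% (13.8 to 17.0). The direction therefore turned with the measure, also among the 3543 genes with a single peak, at -0.07 by fold enrichment and 0.13 by tags.

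**Figure D4:**
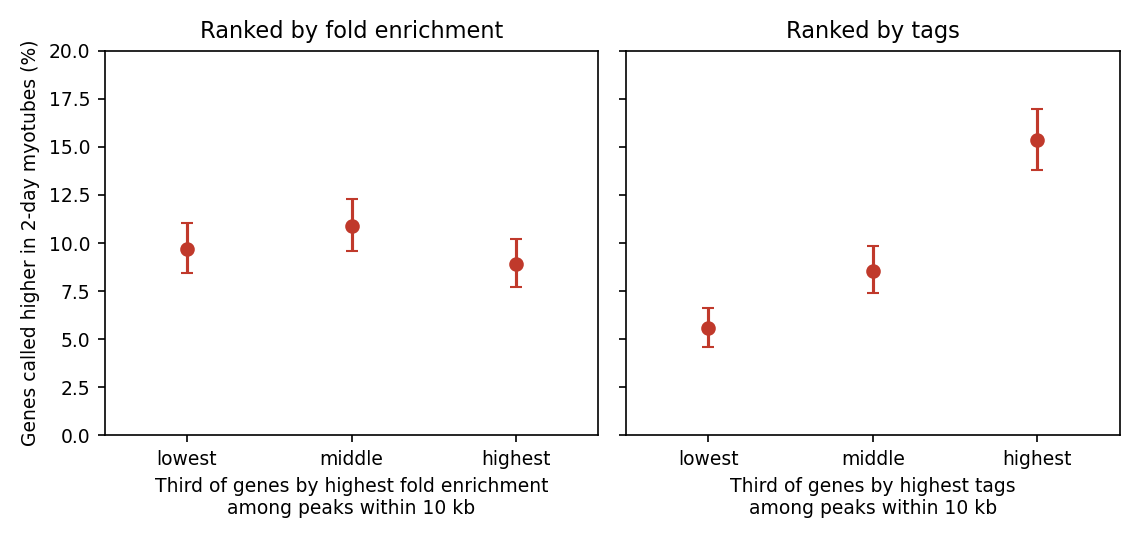
Percent of genes called higher in 2-day myotubes in 3 equal groups of genes by peak height, with exact 95% binomial intervals; height is fold enrichment on the left and tags on the right. The share stays between 8.91% and 10.9% by fold enrichment and runs from 5.57% to 15.4% by tags.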

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

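The tests on chromosome 14 and on the Myod1 peak were chosen only after the result was seen. Both tests on genes called higher were also added after seeing the data. For both tests on genes called higher, what each would show was set down before its own values were seen. For the tests on chromosome 14 and on the Myod1 peak, this was set down after values had been seen.

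Among the 104 genes whose test failed in the authors' deposited table and which entered no comparison, 61 had values above 0 in both conditions and an FPKM of at least 10. Of these, 11 differed by at least 4-fold, a signal outside the tested genes, with no error or control to set it against. Higher in myotubes were Pacsin3 (56.6 to 486 FPKM), Pfkm (42 to 330), Dysf (37.6 to 286), Smyd1 (52.7 to 334) and Atf5 (58.2 to 286) in the authors' deposited table. Pfkm and Dysf, muscle phosphofructokinase and dysferlin, belong to the fixed metabolism and sarcolemma lists and are missing from those counts for this reason. Lower were Reln, Flna, Ephb6, Cad, Snora73a and Snora73b.

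Genes called higher in myotubes carried MyoD peaks more often than matched genes. Loci shared between tested genes do not account for this as a whole. Among genes with a locus of at most 200 kb that no other tested gene shares, the share was 51.8%, against 36.1% in matched sets, above all of them. Loci merged with untested genes were not removed by this restriction, so a part played by them was not tested. Matching on 2-day FPKM in place of the mean did not remove the difference either: the share was 58.6% against 45.9%, again above all matched sets. This matching used 10 bins of FPKM, within which genes can still differ in expression. A part played by activity in myotubes is therefore not excluded. It remains a hypothesis, found and tested on the same data, that MyoD binding may mark genes that rise in differentiation beyond their expression level. Binding was measured in myotubes alone, so whether it came before or after the rise was not tested.

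Chromosome 14 carried few MyoD peaks. A shortage of expressed genes would not account for it, since it had 0.345 peaks per tested gene, below the lowest other autosome at 0.543. Lower tag coverage may account for it: its peaks had a median fold enrichment of 20.0, above the highest other autosome at 15.9, with 10 median tags against 13 to 15, a profile like that of chromosome X. A lower copy number of chromosome 14 in the cells and tags lost in processing would both lower coverage, and no table here separates them. No biological explanation was tested, because the design names no group that differs in chromosome 14.

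The Myod1 peak held the most tags of any peak, 707 against 231 for the next, and covered 80.4% of the Myod1 locus. Its tags were 132 times the genome-wide rate but the authors' fold enrichment was 10.3, a ratio of 12.9 at percentile 99.9 of all peaks. A raised background in the control at this place would give such a ratio. Over all peaks, however, this ratio and the tags had a Spearman rho of 0.53. The Myod1 peak was picked for its tags, so its high percentile is partly set by that choice. Its width was 2464 bp, against a median of 426 bp for all peaks and a 95th percentile of 2503 bp for the next 100 peaks by tags, which are not known to be single sites, so whether MyoD bound at 1 site or several was not settled. Extra copies of Myod1 sequence, such as a construct, or chromatin that is open in the control may each raise both libraries, and stay open. No biological explanation was tested.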

How the results depend on the processing

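Alternatives that used centred calls, own loci, other chromosomes or 2-day matching were chosen only after the data were seen. Of the main results under each alternative, 45 kept their sign and either their side of the threshold, their place in the main interval or a count within 1.5 times the main one, 14 moved, 1 lost its call and 3 changed sign. With own loci, however, the interval of the height rho (-0.066 to 0.0017) and that of the median log2 ratio with 3 or more summits (-0.23 to 0.05) covered 0, which the main ones did not. Of list medians 91 kept their side of the random range and 1 (myogenic regulators without the filter) lost its call. Of those kept, a pair inside the range changed sign: smooth muscle markers without the filter, at 0.04 (main -0.59), and endothelial markers after centring, at 0.21 (main -0.16). Centring of list ratios moves a list and its random lists alike, so no list could change side by it. The counts of lists outside their range after centring were fixed for the same reason. Calls recomputed without centring only repeat the deposited ones. Of list occupancies 85 held, 8 lost their call, 5 gained one and 1 reversed. Genes called higher numbered 1587 after centring (main 1041), and genes called lower 1630 after centring and 1776 at a q of at most 0.01 (main 2769), where the stricter threshold itself removes genes. The peak set held 2189 peaks at a p score of at least 100 and 1 at a false discovery rate of at most 1% (main 10756). Summits at tested genes were 53.2% with a window of 0 kb, 62.8% with 5 kb, 81.4% with 50 kb and 65.6% for peaks with a p score of at least 100. Genes called lower with a peak stayed at 38.3% without matching, but then at percentile 24.6. Among genes with 3 or more summits, 11.4% were called higher with a 50 kb window and 16.7% with own loci (main 13.8%). The rho of height with expression (main -0.03) turned positive at 0.16 by tags and 0.077 by p score. With a 50 kb window it was 0.0069, with an interval of -0.013 to 0.027 that covers 0 and treats genes as independent, so that no direction was shown. Lists above their matched sets in occupancy numbered 2 with a window of 0 kb, 3 with 50 kb and 3 at a p score of at least 100, and 7 with own loci (main 5, ties split evenly), and the adipocyte markers reversed to 0% at that score. Where no cause is stated, the cause was not tested. No paired analysis was possible because each group had 1 sample, and for the same reason no sample could be left out. The E-box alternatives were not run, since they need the mm9 genome sequence. Expression depth limits low genes most: the median SE was 0.76 on the log2 scale below a mean of 10 FPKM and 0.51 above.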

Other observations

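Noncoding RNAs of the H19 region on chromosome 7 and genes near tag-rich MyoD peaks were examined after the values were seen. H19, an imprinted noncoding RNA abundant in myoblasts, rose from 8036 to 35132 FPKM (log2 2.13, SE 0.62, q = 0.00466) in the authors' deposited table and had 1 summit within 10 kb. Nctc1, a neighbouring noncoding transcript, rose from 1.27 to 6.94 FPKM (log2 2.45, SE 0.54, q = 8.58e-05) in the authors' deposited table and had 2 summits within 10 kb, of which the larger held 110 tags. Actc1 rose from 280 to 6148 FPKM (log2 4.46, SE 0.66) in the authors' deposited table with 3 summits. Chrna1, also with 3 summits, was at 327 and 387 FPKM and was not called.

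Also examined after the values were seen, 47 peaks, that at Myod1 among them, had tags over the genome-wide rate at more than 5 times the authors' fold enrichment. The highest ratio, 39.2, was at a peak of 256 bp and 83 tags on chromosome 19 from 4989055 to 4989310. Over all peaks this ratio and the tags had a Spearman rho of 0.53.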
